A study of Rattus norvegicus with 8 samples.

How the data were processed

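Liver RNA from 21-day-old male rats, pooled from 2 pups per array, was hybridised to 8 Agilent arrays as part of a study of 72 arrays, of which the other arrays were not analysed here. Per the labels' protocols, 200 ng of total RNA was amplified, the sample was labelled with Cy5 and universal rat reference RNA from 14 cell lines with Cy3, and all 8 arrays had the same dye orientation. Dye bias is therefore shared by both groups and not measured. Groups were taken from the sample labels, 4 control and 4 mixture arrays. Control pools were numbered 5 to 8 and mixture pools 1 to 4, so no number was shared between the groups.

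Spot intensity values came from Agilent Feature Extraction 11.0.1.1, per the file headers. The deposited intensity columns used were the median foreground and median background signals of each channel, since mean signals were not among the columns used here, and the design fixed before the data were examined had named mean signals. Marks for spots well above background, saturated or outlying were taken from the deposited files as well. The deposited value table held log2 ratios of Cy5 over Cy3, whose making by the authors is not given in the sources used here. On each array it correlated with r of 0.997 to 0.998 with loess-normalised log2 ratios without background correction, with a slope of 0.996 to 1.00, so its scale and direction were settled from the scanner values. Its column medians lay between -0.0389 and -0.0326, and its centring method stayed unknown. It served as an alternative.

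In R 4.3.3 with limma 3.58.1, background was corrected with normexp and an offset of 50, and each array was normalised with loess, with control spots given no weight. Spots marked as outliers by the scanner software were left out and spots of a probe were averaged. On each array 771 to 956 spots were marked as outliers. With control spots left out but outlier spots still counted, the 58717 spots of an array represented 30367 probes. Of these, 18005 received a gene symbol by matching their accession to a RefSeq gene table of assembly GRCr8, used for names only, and other probes kept their probe name. A probe was tested if it was well above background in Cy5 on at least 3 of the 4 arrays of a group, which 11406 probes were. The brightest probe represented each gene, giving 10566 genes or unnamed probes, 6938 with a symbol. Signal over background thus set which genes could be measured.

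Groups were compared on log2 ratios with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. All adjusted p-values of single genes are limma's. Gene lists, 39 in number, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation as the alternative, where at least 5 members were measured (35 lists). Members were also adjusted over their list alone. fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, gave an adjusted p under the threshold for 2 lists, AhR targets (0.0124) and CAR and PXR targets (0.0124). With slide column fitted, fry gave an adjusted p of 0.0106 for AhR targets and 0.0316 for CAR and PXR targets. Overlapping list members include Nqo1, Me1, Ugt1a6, Aldh1a1, Cyp2c7 and Cyp1a2, the last also a pericentral hepatocyte marker. Reference signals were compared in Cy3 alone after normexp and quantile normalisation. Slide row and column came from the position suffix of each array's scan, and all arrays were scanned together.

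Named genes followed a rule fixed before the data were examined. It took up to 15 named genes in each direction past the threshold with non-overlapping groups or, with under 5 past it in a direction, the 5 with the smallest unadjusted p, given as values. It added members of the AhR and CAR and PXR lists past the threshold overall or over the list alone, a fixed set of P450 and related genes, up to 4 members of every other list past the threshold (otherwise up to 2 past it over the list alone or, for lists past camera's threshold, the 2 with the smallest p), and Dnmt1. A further gene that the rule took is not reported here. Where a gene was not well above background on any array of a group, the fold was bounded after loess and Aquantile, with the lowest signal well above background as floor, and such a bound is open to dye bias.

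The fits were tested on simulated data with the real means, slide column differences and residual spreads of 10565 genes. Without slide column in the fit, 64% of 100 genes changed by 1 on the log2 scale and 99% of 100 genes changed by 2 were recovered, with 1 false call. With slide column fitted, 98% and 100% were recovered, with 12 false calls. The simulated genes varied independently, and far more of them changed than passed in the real data, which eases the adjustment. These shares therefore need not hold for the real arrays, where Cyp2b2 at 2.04 missed the threshold without slide column in the fit. Alternatives covered background correction, normalisation, use of Cy5 alone, filters, probe choice, outlier spots kept, slide row and column, the variance model, the deposited table and leaving out each array. Single-column subsets, combinations with slide column and list tests with slide column were added after the data were examined.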

Results

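Hepatic gene expression was measured in 21-day-old male Sprague-Dawley rats whose mothers had been dosed through pregnancy and nursing. The control group came from dams given the corn oil vehicle. The mixture group came from dams given organochlorine pesticides, polychlorinated biphenyls and methyl mercury at 0.5 mg/kg/day together with agonists of the aryl hydrocarbon receptor (AhR), at a total dioxin-equivalent dose of 6.3 ng/kg/day. The AhR is a ligand-activated transcription factor that responds to dioxins and related planar compounds. Liver RNA of 2 pups was pooled for each array, so that 8 pups of each group gave 4 control arrays and 4 mixture arrays. Each array carried the sample in Cy5 and a common reference RNA from 14 rat cell lines in Cy3. The comparison asked which liver genes differed between the offspring of mixture-treated and vehicle-treated dams. Litter membership of the pups was not given in the sources used here, so the p-values measure the spread between pools.

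The median Cy5 signal lay between 81 and 94 intensity units over the 8 arrays, above median backgrounds of 68 to 73. Between 42.9% and 49.2% of spots were well above background in Cy5, and between 64.3% and 67.8% in Cy3. No spot was saturated. With 4 arrays in a group, the number of arrays limits the precision. The arrays lay on 1 slide in 2 columns, each with 2 control and 2 mixture arrays. Arrays of the same column correlated with r of 0.981 to 0.991 across genes, and arrays of different columns with r of 0.938 to 0.962. The first principal component held 69.1% of the variance and separated the columns. The log ratio of 5990 of 10566 genes differed between the columns past an adjusted p of 0.05. Slide column was therefore also fitted, and values within each column are given for the lists and the main genes. Of 51 named genes, 50 had the same sign in both columns, Cox5b being the exception, 7 differed between the columns by over 1.5-fold, and 3 passed the threshold with slide column fitted. Most of these genes were named by their values over these same arrays, so the shared signs are no independent check.

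**Figure D1:**
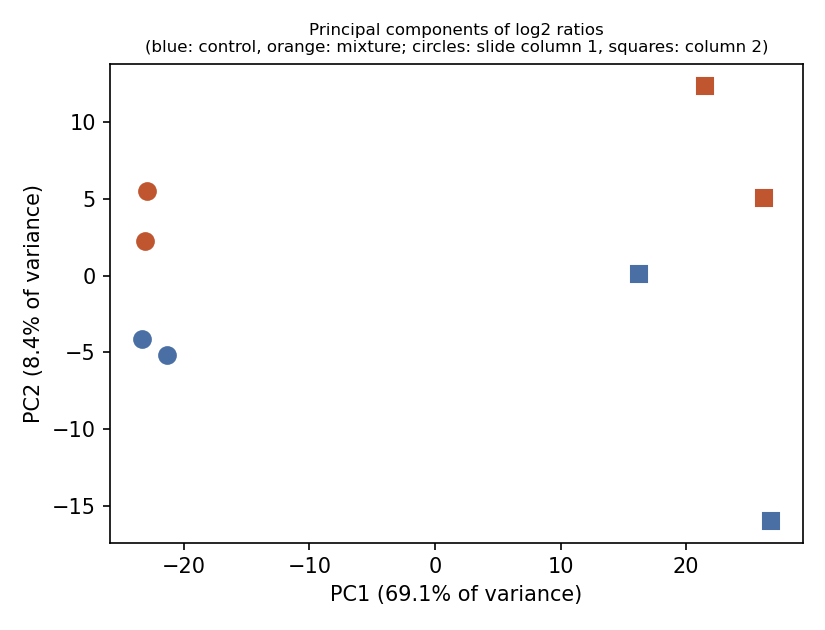
Principal components of the log2 ratios of the 8 arrays, with the first component (69.1% of variance) on the x axis and the second (8.41%) on the y axis. Each point is 1 array, blue for control and orange for mixture, with circles for slide column 1 and squares for column 2, and the 2 columns separate along the first component.

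Cyp1a1, the cytochrome P450 classically induced through the AhR, rose in the mixture group. Its log2 ratio to the reference was 0.90 ± 0.53 (SD, n = 4) in control livers and 4.93 ± 0.58 (SD, n = 4) in mixture livers, a 16.4-fold difference. The difference was 4.04 on the log2 scale (SE 0.33, adjusted p = 0.00919), and every mixture array lay above every control array. It was the 1 gene of 10566 past the threshold without slide column in the fit. Its probe was well above background on 3 of the 4 control arrays and all 4 mixture arrays. The difference was 4.29 in slide column 1 and 3.78 in column 2, and the adjusted p was 0.00268 with slide column fitted. With it fitted, Cyp1a1 also passed without each single array, with adjusted p of 0.000956 to 0.0278. When slide column was not fitted, leaving out some single arrays lost the call. The adjusted p was then 0.0594 without control replicate 5, 0.0733 without control replicate 7, 0.0564 without mixture replicate 2 and 0.0662 without mixture replicate 3. Without mixture replicate 1 there were 2 genes, the second being Ceacam4 with an adjusted p of 0.0223. The Cyp1a1 difference stayed between 3.84 and 4.30 whichever array was left out, but its size moved with the processing, to 3.07 with median centring, 3.09 in Cy5 alone (8.50-fold), 4.67 with an offset of 16 and 5.20 with the scanner software's processed signals. The adjusted p was 0.163 with processed signals, 0.162 with slide row as a block, where the difference was 4.04, and 0.199 over column 2 alone. In every slide row the groups lay in different columns. The fit with slide row therefore kept the column differences in its residual spread.

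With slide column fitted, 5 genes passed the threshold, all higher in the mixture group. Besides Cyp1a1 they were Cyp2b2, Ceacam4, Cyb5a and a probe with no gene name here (A_64_P057526). Cyp2b2, a P450 induced by phenobarbital-type compounds through the constitutive androstane receptor, differed by 2.04 on the log2 scale (SE 0.25, adjusted p = 0.0286), or 4.11-fold. It differed by 2.15 in column 1 and 1.93 in column 2, a second Cyp2b2 probe differed by 1.51, and with processed signals the difference was 0.70 (adjusted p = 0.463). Its adjusted p was 0.0762 without background correction, 0.179 with an offset of 16, 0.0711 with the deposited values and 0.106 with a trended robust variance. It was 0.0830 without control replicate 5, 0.107 without control replicate 8, 0.0840 without mixture replicate 1, 0.124 without mixture replicate 3 and 0.132 without mixture replicate 4, so that Cyp2b2 passed in 3 of the 8 fits without 1 array. Ceacam4 differed by 1.64 (SE 0.18, adjusted p = 0.0192), with 1.996 in column 1 and 1.28 in column 2. Its adjusted p was 0.0547 with median centring, 0.1001 with processed signals, 0.0908, 0.0968 and 0.0520 without control replicate 5, 6 and 7, and 0.124 and 0.123 without mixture replicate 3 and 4. Cyb5a, cytochrome b5, an electron donor to P450 enzymes, differed by 0.54 (SE 0.06, adjusted p = 0.0192) and passed without 1 array only when that was mixture replicate 2, with adjusted p of 0.0520 to 0.132 otherwise. Its adjusted p was 0.1001 with processed signals, 1.00 with median centring and 0.106 with a trended robust variance. The unnamed probe differed by 0.92 and had an adjusted p of 0.0516 to 0.123 without single arrays other than control replicate 7 and mixture replicate 2, and of 0.1001 with processed signals and 0.635 with median centring. Cyb5a and the unnamed probe lie outside the rule for named genes and were chosen after their values were seen. The count moved with single arrays: it was 1 without control replicate 5, mixture replicate 3 or mixture replicate 4, 2 without control replicate 6, control replicate 8 or mixture replicate 1, 8 without control replicate 7 and 11 without mixture replicate 2, and it was 0 with processed signals, where 860 genes had an unadjusted p under 0.05 in limma. Cyp1a1 passed without each of the 8 arrays. Without slide column in the fit these genes missed the threshold, with adjusted p of 0.504 for Ceacam4, 0.789 for A_64_P057526 and 1.00 for Cyp2b2 and Cyb5a.

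**Figure D2:**
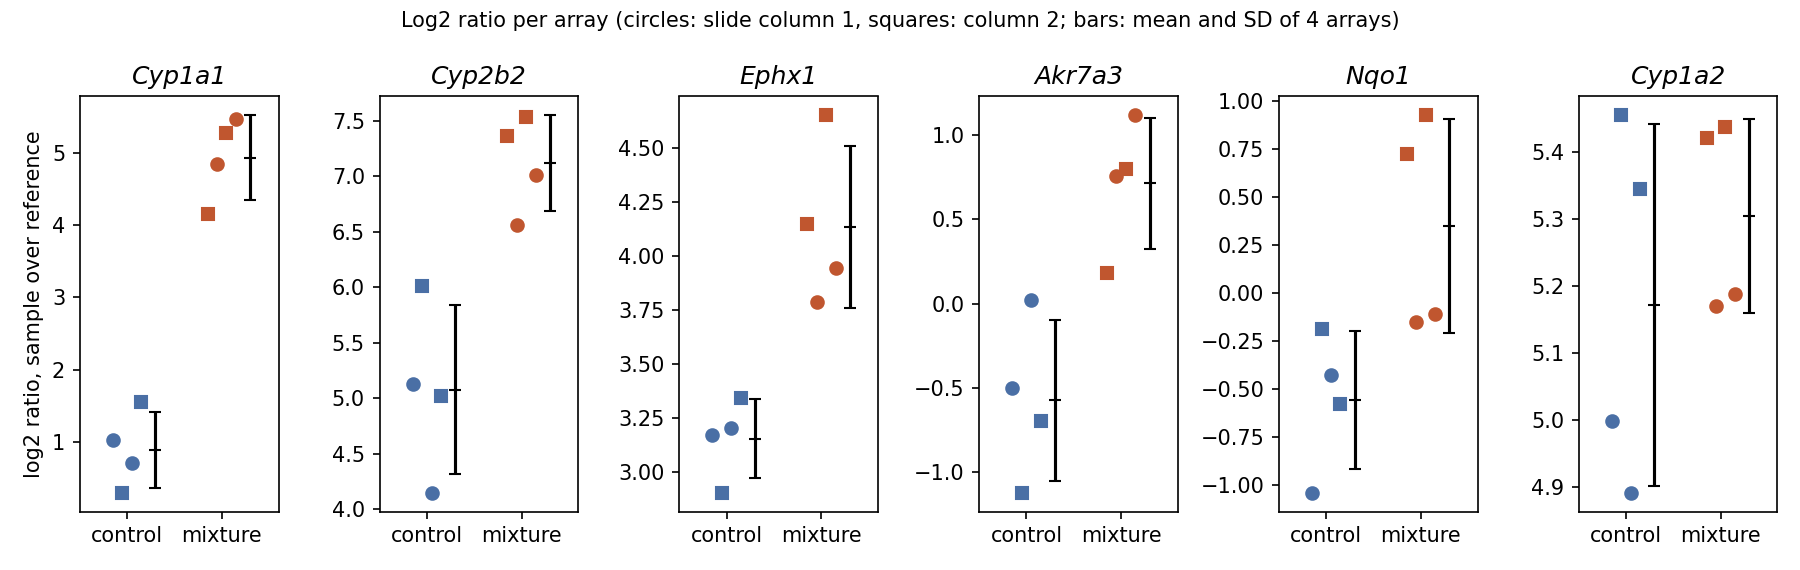
Log2 ratio of sample over reference on each of the 8 arrays for 6 genes, each panel with its own y axis, with points for arrays (blue control, orange mixture; circles slide column 1, squares column 2) and black bars for the mean and SD of 4 arrays. Cyp1a1 had means of 0.90 and 4.93, whereas the means of Cyp1a2 were 5.17 and 5.30.

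Of the AhR target list, 8 of 12 genes were measured, 7 of them higher in the mixture group. Adjusted over the list alone, 3 passed, all higher, against 1 when adjusted over all genes. Besides Cyp1a1 these were Nqo1, a quinone reductase, with a difference of 0.91 (SE 0.28, adjusted p = 0.0304 over the list alone), and Ugt1a6, a phenol glucuronosyltransferase, with 0.52 (SE 0.16, adjusted p = 0.0304 over the list alone). The difference of Nqo1 was 0.60 in column 1 and 1.21 in column 2, and that of Ugt1a6 0.56 and 0.48. Over the list alone, Nqo1 missed the threshold without control replicate 5 (adjusted p = 0.0877), 7 (0.0701) or 8 (0.0831) or mixture replicate 1 (0.0896) or 3 (0.0821), and Ugt1a6 without control replicate 7 (0.0701) or 8 (0.0831) or mixture replicate 2 (0.0669), 3 (0.0821) or 4 (0.0864). Both passed over the list alone without each array when slide column was fitted. The list, which holds Cyp1a1 and was not tested without it, rose (camera adjusted p = 1.96e-09). With an estimated correlation camera gave adjusted p = 0.0114. With slide column fitted as well, the adjusted p with an estimated correlation was 0.0603. Its median difference was 0.23, with 0.32 in column 1 and 0.29 in column 2. Since each column held 2 arrays of each group, fitting slide column left the differences themselves as they were. Cyp1b1 was not well above background on any control array and on 1 mixture array, and Ahrr on no array, so neither was tested. Tiparp had no named probe here.

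Cyp1a2, a further AhR target, had a log2 ratio of 5.17 ± 0.27 (SD, n = 4) in control and 5.30 ± 0.14 (SD, n = 4) in mixture livers, a difference of 0.13 (SE 0.15, adjusted p = 1.00) that turned to -0.16 with the processed signals and -0.03 with the deposited values. In Cy5 alone it was 2.90-fold higher in the mixture group (log2 difference 1.54), with an adjusted p of 0.129, or 0.000135 with slide column fitted. The Cy3 reference signal at the same probe was also higher on the mixture arrays, by 1.38 on the log2 scale (adjusted p = 0.00253). It was the 1 gene past the threshold in the reference channel, although by the labels all 8 arrays carried the same reference RNA. The net Cy3 signal averaged 261 ± 28.2 (SD, n = 4) on control arrays and 769 ± 110 (SD, n = 4) on mixture arrays. After normalisation the Cy3 signal was 2.45-fold higher in column 1 and 2.77-fold higher in column 2. Without mixture replicate 2, 4 genes passed in the reference channel. Over all arrays, Cy3 differences that missed the threshold were 0.70 for Apoa2, 0.67 for Cyp2c6v1, 0.40 for Cyp2c7 and 0.31 for Cyp2b2. For Cyp1a1 and Cyp3a23-3a1 the Cy3 difference was 0.02 each, and for Saa4 it was -0.17.

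**Figure D3:**
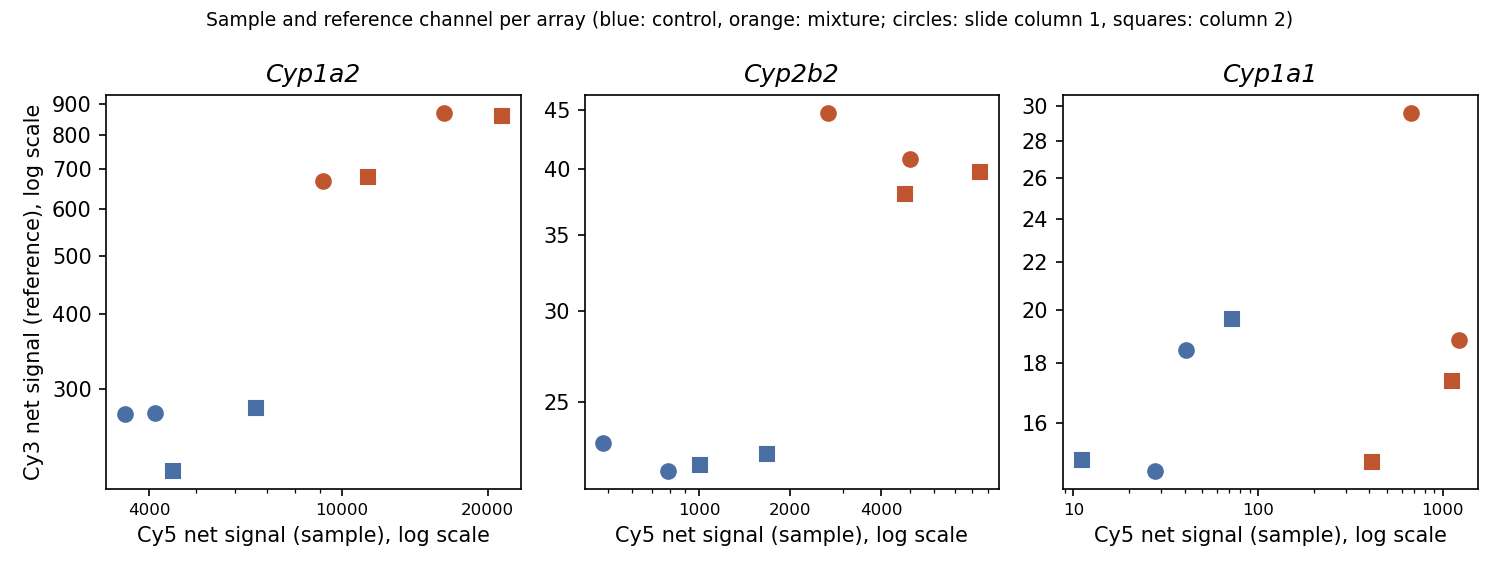
Net Cy5 signal of the sample (x axis, log scale, intensity units) against net Cy3 signal of the reference (y axis, log scale, intensity units) at the probes of Cyp1a2, Cyp2b2 and Cyp1a1, where each point is 1 array, blue for control and orange for mixture, with circles for slide column 1 and squares for column 2. For Cyp1a2 the mean Cy3 signal was 261 on control and 769 on mixture arrays.

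Drug-metabolising genes regulated by the constitutive androstane and pregnane X receptors (CAR and PXR) rose as a group, with a camera adjusted p of 3.30e-16, or adjusted p = 0.00595 with an estimated correlation. When slide column was fitted too, the camera call with an estimated correlation was lost (adjusted p = 0.0603), while the preset correlation gave adjusted p = 2.80e-11. Of 28 listed genes 22 were measured, 17 of them higher in the mixture group, with a median difference of 0.32 (0.39 in column 1 and 0.35 in column 2). Adjusted over the list alone, 9 passed in limma, all higher, against 0 when adjusted over all genes and 9 at an unadjusted p under 0.05. The largest were Cyp2b2 with 2.04, the retinol-oxidising P450 Cyp2c7 with 1.63 (SE 0.46, adjusted p = 0.0231 over the list alone), the aflatoxin aldehyde reductase Akr7a3 with 1.29 (SE 0.26, adjusted p = 0.00647 over the list alone) and the retinal dehydrogenase Aldh1a1 with 1.14 (SE 0.37, adjusted p = 0.0333 over the list alone). In columns 1 and 2 the differences were 1.03 and 2.23 for Cyp2c7, 1.18 and 1.40 for Akr7a3 and 0.54 and 1.75 for Aldh1a1. Further Cyp2c7 probes differed by 1.96 and 1.70. Microsomal epoxide hydrolase Ephx1 differed by 0.98 (0.68 in column 1, 1.28 in column 2), the glutathione transferases Gsta5 and Gstm1 by 0.67 and 0.45, and the canalicular exporter Abcc2 by 0.42. The carboxylesterase Ces2h was not well above background on any control array and was so on 3 mixture arrays, at least 1.24-fold higher. Ces2h, 1 of the 9 genes, thus entered the test through the mixture arrays alone, the group where it was higher. The PXR target listed as Cyp3a1, named Cyp3a23-3a1 here, differed by 0.09 (SE 0.14), or -0.01 with processed signals. Cyp3a9 was not well above background on any array, and Cyp2b1 had no named probe here. Of the 9 genes, 4 passed over the list alone without control replicate 6 and 5 without mixture replicate 3 or 4, whereas Cyp2b2, Akr7a3, Ephx1 and Abcc2 passed without each array. Cyp2c7 missed it without control replicate 6 (adjusted p = 0.0688) or mixture replicate 4 (0.0566), and Aldh1a1 without control replicate 6 (0.0688) or 8 (0.0865) or mixture replicate 3 (0.0829) or 4 (0.0894). Gstm1 missed it without control replicate 5 (0.0879), 6 (0.0906) or 8 (0.0612) or mixture replicate 2 (0.0965), 3 (0.0729) or 4 (0.0894), Gsta5 without control replicate 6 (0.0827) or 7 (0.0738) or mixture replicate 1 (0.0650) or 3 (0.0729), and Ces2h without control replicate 6 (0.0590) or mixture replicate 3 (0.0558) or 4 (0.0566). When slide column was fitted, 10 genes passed over the list alone, and each of them did so without each array.

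Gstm2, a glutathione transferase outside these lists, was among the 5 named genes with the smallest unadjusted p among the higher ones, at 0.83 (SE 0.16, adjusted p = 1.00). The 5 lower genes with the smallest unadjusted p were Nampt at -0.57, Btg1 at -0.55, Wsb1 at -0.50, Rsrp1 at -0.46 and Cyp2d1 at -0.40, all with adjusted p = 1.00. In columns 1 and 2 the differences were 0.80 and 0.85 for Gstm2, -0.72 and -0.41 for Nampt, -0.47 and -0.62 for Btg1, -0.27 and -0.72 for Wsb1, -0.45 and -0.48 for Rsrp1 and -0.21 and -0.59 for Cyp2d1. At an unadjusted p under 0.05 there were 164 genes, 118 higher and 46 lower, without slide column in the fit and 659, 382 higher and 277 lower, with it, against about 528 that chance gives. With median centring these counts were 67 without slide column in the fit and 184 with it. In the fits without slide column, differences between the columns counted as spread within each group and made p-values larger. The 164 genes are therefore no sign of fewer changes than chance gives. The groups did not overlap for 140 genes, or 1.32% of those tested, against 2.86% that chance gives for exchangeable arrays, which the slide columns do not leave. In a comparison chosen after the data were examined, the other 17 splits with 2 arrays of each column on each side gave 45 to 179 genes without overlap and 223 to 846 genes at an unadjusted p under 0.05 with slide column fitted.

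Genes of antioxidant defence, lipid metabolism and glucose metabolism made up 5 of a further 16 lists that had a camera adjusted p under 0.05 with the preset correlation. Of all 18 lists, 17 kept it with slide column fitted, glucose metabolism being the exception. None of the 16 kept it with an estimated correlation, where camera gave 2 lists in all and 9 at an unadjusted p under 0.05. Antioxidant genes induced through NRF2 were higher in 14 of 18 members (median 0.22; 0.20 in column 1, 0.22 in column 2), with adjusted p = 2.01e-07, but adjusted p = 0.108 with an estimated correlation. Adjusted over the list alone, 0 passed in limma, and 4 had an unadjusted p under 0.05, with the smallest p for Nqo1 at 0.91 and the malic enzyme Me1 at 0.67. All 25 cholesterol synthesis genes were higher (median 0.33; 0.18 in column 1, 0.58 in column 2), with Mvd at 0.64 (SE 0.48), Msmo1 at 0.90 (SE 0.73; 0.12 without control replicate 6) and adjusted p = 1.73e-05, but adjusted p = 0.468 with an estimated correlation. The mean over these members, relative to the control mean, was -1.40 on control replicate 6 and between 0.02 and 0.71 on the other control arrays. Without that array the direction of the list turned (adjusted p = 0.0907). Lipogenic genes were higher in 12 of 15 (median 0.14; 0.12 in column 1, 0.33 in column 2), with Me1 and the elongase Elovl6 as examples and adjusted p = 0.00288, but adjusted p = 0.414 with an estimated correlation. Elovl6 was at 0.53 (0.23 in column 1, 0.84 in column 2), and its second probe gave 0.25. The direction of the list turned without control replicate 6 (0.828), and the adjusted p was 0.0872 without mixture replicate 2.

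Fatty acid oxidation and ketogenesis genes were lower in 25 of 30 (median -0.14; -0.07 in column 1, -0.22 in column 2), with the dienoyl-CoA reductase Decr1 at -0.27, the lipase inhibitor Angptl4 at -0.30 and adjusted p = 2.22e-05, but adjusted p = 0.187 with an estimated correlation. Glucose metabolism genes were lower in 8 of 13 (median -0.10; -0.09 in column 1, -0.13 in column 2), with the gluconeogenic enzymes Fbp1 at -0.20 and G6pc1 at -0.29, whose second probe gave -0.03. The list's adjusted p was 0.0358, but adjusted p = 0.290 with an estimated correlation and 0.112 with slide column fitted. It was 0.265 without control replicate 7, 0.171 without control replicate 8, 0.0995 without mixture replicate 1, 0.281 without mixture replicate 2 and 0.110 without mixture replicate 3.

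Growth hormone and IGF genes were lower in 12 of 14 (median -0.12; -0.09 in column 1, -0.28 in column 2), with adjusted p = 0.000360, but adjusted p = 0.155 with an estimated correlation. The fetal growth factor Igf2 was at -1.19 (SE 0.45), with -0.25 in column 1 and -2.13 in column 2. Insr, the insulin receptor, was at -0.30, with -0.14 in column 1 and -0.46 in column 2. Its probe was well above background on 4 control but only 2 mixture arrays. A second Insr probe, which missed the signal filter, gave -0.04. In the thyroid hormone list 7 of 11 were higher (median 0.04; 0.09 in column 1, 0.03 in column 2), with adjusted p = 0.00281, but adjusted p = 0.118 with an estimated correlation, 0.0592 without control replicate 6 and 0.0595 without mixture replicate 4. This list shares Ugt1a6 (0.52) with the AhR list and Me1 (0.67) with the NRF2 and lipogenesis lists, and its mean difference was 0.20. Its sulfotransferase Sult1b1 passed at 0.83 (SE 0.21, adjusted p = 0.0407 over the list alone), the 1 member to do so, against 0 over all genes and 3 at an unadjusted p under 0.05 in limma. It missed that threshold without control replicate 5 (adjusted p = 0.0542), 6 (0.0733) or 8 (0.0936) or mixture replicate 1 (0.0657), 3 (0.134) or 4 (0.0773), but passed without each array when slide column was fitted.

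Cell cycle genes were higher in 23 of 26 (median 0.11; -0.04 in column 1, 0.26 in column 2), with adjusted p = 2.22e-05, but adjusted p = 0.285 with an estimated correlation and 0.0905 without control replicate 8. The mitotic drivers Ccna2 and Cdk1 were both at 0.26, and a second Ccna2 probe gave 0.05. Respiratory chain subunits were lower in 18 of 22 (median -0.07; 0.01 in column 1, -0.14 in column 2), with Ndufb8 at -0.25, Cox5b at -0.14 (0.01 in column 1) and adjusted p = 0.0154, but adjusted p = 0.155 with an estimated correlation. The list's adjusted p was 0.0514 without control replicate 6, 0.226 without control replicate 8, 0.0513 without mixture replicate 2 and 0.0845 without mixture replicate 4. Ribosomal proteins were lower in 20 of 21 (median -0.08; 0.02 in column 1, -0.18 in column 2), with Rpl11 at -0.15, Rpl7 at -0.16 and adjusted p = 0.00281, but adjusted p = 0.319 with an estimated correlation, 0.118 without control replicate 8 and 0.139 without mixture replicate 1.

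Acute phase genes were lower in 16 of 22 (median -0.13; -0.11 in column 1, -0.11 in column 2), with the lipopolysaccharide-binding protein Lbp at -0.49, Saa4 at -0.24 and adjusted p = 0.000562, but adjusted p = 0.263 with an estimated correlation and 0.306 without control replicate 7. Interferon-induced genes were higher in 15 of 20 (median 0.21; 0.20 in column 1, 0.05 in column 2), with Ifi27 at 1.08, the immunoproteasome subunit Psmb8 at 0.33 and adjusted p = 0.000136, but adjusted p = 0.270 with an estimated correlation.

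Among cell type markers, those of hepatocytes were lower in 15 of 17 (median -0.15; -0.07 in column 1, -0.27 in column 2), with adjusted p = 0.00229, but adjusted p = 0.145 with an estimated correlation. The urea cycle enzyme Cps1 was at -0.35 (-0.07 in column 1, -0.62 in column 2), while the apolipoprotein Apoa2 was at 0.45, or -0.19 with processed signals and 1.201 in Cy5 alone. Periportal hepatocyte markers were lower in 9 of 10 (median -0.20; -0.10 in column 1, -0.28 in column 2), with Hsd17b13 at -0.19 and adjusted p = 0.00229, but adjusted p = 0.108 with an estimated correlation and 0.0514 without control replicate 6. Kupffer cell and macrophage markers were higher in 12 of 13 (median 0.15; 0.19 in column 1, 0.07 in column 2), with Adgre1 at 0.36, Cd5l at 0.37 and adjusted p = 0.00287, but adjusted p = 0.285 with an estimated correlation, 0.112 without control replicate 5 and 0.213 without mixture replicate 3. Neutrophil markers were lower in 6 of 6 (median -0.40; -0.14 in column 1, -0.65 in column 2), with S100a9 at -0.40, Defa5 at -0.56 and adjusted p = 0.00675, but adjusted p = 0.270 with an estimated correlation. Their adjusted p was 0.213 without control replicate 6, 0.258 without control replicate 7 and 0.0516 without mixture replicate 4.

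Lymphocyte markers had an adjusted p of 0.104, or 0.0367 without mixture replicate 3, and the chemokine Ccl5 passed at 0.62 (SE 0.15, adjusted p = 0.0182 over the list alone). Ccl5 missed it without control replicate 7 (adjusted p = 0.0510) or 8 (0.0590) or mixture replicate 3 (0.0618) or 4 (0.0620), but passed without each array when slide column was fitted. The other marker lists missed the threshold, with adjusted p of 0.205 for pericentral hepatocytes (0.0179 without mixture replicate 2), 0.560 for endothelial cells, 0.601 for stellate cells and fibroblasts and 0.186 for erythroid cells (0.0188 without mixture replicate 1). Too few markers of cholangiocytes (4), pancreatic acinar cells (2), skeletal muscle (3) and adipocytes (4) were measured for a test, and their median differences were 0.02, 1.46, -0.01 and -0.11.

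Of the other 12 pathway lists, which missed the threshold, fetal liver genes had the smallest adjusted p, 0.0981, with a median of -0.29 over 5 genes, and 0.0192 without control replicate 7 or 0.00632 without mixture replicate 3. The adjusted p was 0.147 for sex-dependent liver genes, and 0.00829 without control replicate 7 or 0.00548 without mixture replicate 2. It was 0.197 for p53 targets, 0.321 for the glucocorticoid response, 0.445 for heme and iron, 0.460 for metallothioneins and zinc transport and 0.518 for methylation and one-carbon metabolism. For bile acids it was 0.601, for immediate early genes 0.870, for retinoid metabolism 0.950, and for the circadian clock and ER stress 0.966 each. The retinoid list had a median of -0.08 and a mean of 0.09, and the clock list a median of -0.13 and a mean of 0.04, with the test's direction up for the first and down for the second. The maintenance DNA methyltransferase Dnmt1 was not well above background on any array.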

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

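The counts over other splits for genes with slide column fitted and for lists with an estimated correlation were set before their results were seen. The other tests of this part were chosen only after the result was seen. Over 110 groups of 4 arrays examined for a single array far from the others, 5 stood out, against about 5.5 that chance gives, at 1 in 20 groups. For Gstm2 in the control group, replicate 7 had a log2 ratio of 2.24 and the others 1.90 to 1.95 (gap over range 0.841). For Cyp2d1 in the mixture group, replicate 4 had 6.78 and the others 6.37 to 6.42 (0.886). For Adgre1 in the mixture group, replicate 3 had 2.33 and the others 1.63 to 1.74 (0.848). For Cd5l in the control group, replicate 5 had 2.89 and the others 3.52 to 3.56 (0.939). Control replicate 8 had 64.3% of spots well above background in Cy3 and the other control arrays 67.5% to 67.8% (0.908).

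In the reference channel, outside the comparison of ratios, the Cyp1a2 signal was higher on mixture than on control arrays by 1.38 on the log2 scale. Against a difference of the reference RNA between slide columns, the rise was 2.45-fold in column 1 and 2.77-fold in column 2. Against a fixed share of Cy5 light or sample RNA in the Cy3 channel, Cy3 rose by 5.15% of the rise in Cy5 for Cyp1a2 but by 0.435% for Cyp2b2 and 0.400% for Cyp1a1. A candidate explanation that stays open is that Cy3 follows Cy5 where liver RNA far exceeds the reference: deviations of both channels from their group and column means correlated with r = 0.498 over the 326 genes with a mean log2 ratio over 4, against 0.309, 0.214 and 0.241 for ratios of 2 to 4, 0 to 2 and under 0, but the slope over the 326 genes, 0.228, gives only 25.3% of the Cyp1a2 rise, so its size is not accounted for. No biological explanation was tested, since by the labels all arrays carried the same reference RNA.

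Of the 35 splits of the arrays, 3 gave at least the 1 gene of the real groups in Cy3, so chance cannot be excluded for that count, and the highest other split, that by slide column, gave 4181 and points to a structure of the arrays. The count in Cy3 was again 1 with slide column fitted, and 4 without mixture replicate 2.

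The arrays separated by slide column, with 5990 genes past the threshold. A lower Cy5 signal in 1 column was argued against by the share of spots well above background, whose column means differed by -0.152 percentage points (column 2 minus column 1) with overlapping arrays. A technical difference between the columns remains a candidate: in Cy3, which by the labels held the same reference RNA on every array, 39.6% of the genes tested differed between columns. Whether the same preparation of the reference served both columns is not given in the sources used here. For Calr, net Cy3 signal was 1336 to 1482 in column 1 and 7502 to 8246 in column 2. Differences of Cy5 and Cy3 between columns correlated across genes, which are not independent replicates, with r = 0.119, and different animals in the columns cannot be told apart from sample labelling for the Cy5 part, because each pool lay in 1 column.

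For the comparison of the groups, 2 of the 35 splits of the 8 arrays gave at least 1 gene, the real one and the split by slide column with 5990. The latter follows a structure of the arrays, and each further split gave 0, so this share, which is not under 0.05, decides little about chance. When slide column was fitted, the real groups gave 5 genes and the highest of the other splits with 2 arrays of each column per side gave 0, so that 1 of 18 such splits reached 5. These splits are too few for a share under 0.05. For gene lists with an estimated correlation, 2 of 35 splits gave at least the 2 lists of the real groups, the highest other giving 2, so chance cannot be excluded for that count either. With the preset correlation, 2 of 35 splits gave at least the 18 lists of the real groups, the highest other giving 21, so chance cannot be excluded for that count. Both lie among the 18 splits with 2 arrays of each column per side, of which the other 17 gave 7 to 21 lists with a median of 10.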

How the results depend on the processing

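Alternatives confined to 1 slide column, and those that combine slide column with another choice or with a list test, were chosen after the data were examined. The count of 1 gene, Cyp1a1, stayed at 1 without background correction, with offset 16, median centring, Cy5 alone, outlier spots kept, no filter, every probe on its own, the deposited values, array weights and a trended robust variance. Aquantile left the ratios as they were. The count was 0 with processed signals, with slide row as a block and with the filter on all 8 arrays, where Cyp1a1 was not tested because it was not well above background on 1 control array. At an unadjusted p under 0.05 these gave 600, 78 and 130 genes in limma. It was 5 with slide column as a covariate, 14 with slide column and Cy5 alone, 2 in column 1 alone and 0 in column 2 alone (575 and 597 at an unadjusted p under 0.05), each with 4 arrays. Leaving out 1 array gave 0 to 2 genes, 0 without control replicate 5, control replicate 7, mixture replicate 2 or mixture replicate 3 (153, 151, 178 and 117 at an unadjusted p under 0.05) and 2 without mixture replicate 1. For the other calls the cause was not tested.

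When slide column was fitted, the count of 5 became 0 with processed signals (860 at an unadjusted p under 0.05), 3 with median centring, 14 with Cy5 alone, 3 with the filter on all 8 arrays, 9 with every probe on its own and 3 with a trended robust variance. Leaving out 1 array gave 1 to 11 genes, and Cyp1a1 passed in all 8 cases. The reference channel gave 1 gene throughout, except 4 without mixture replicate 2, so 1 to 4. Of 51 named genes, 4 changed sign under some setting: Cyp1a2 was at -0.161 with processed signals and -0.0308 with deposited values, Cyp3a23-3a1 at -0.0140 and Apoa2 at -0.187 with processed signals, and Cox5b at 0.0141 in column 1 alone. The number of lists past the threshold, 18, became 2 with an estimated correlation, 10 with processed signals and 0 with slide column and an estimated correlation (4 at an unadjusted p under 0.05). Only AhR targets and CAR and PXR targets held with an estimated correlation. No paired analysis by replicate number was possible because the groups share none, while slide row as a block pairs arrays by position, with 1 array of each group in each row. The arrays of a row lay in different columns, so this fit left the column differences in its residual spread. Signal over background left 30367 probes with 11406 that could be compared.

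Camera adjusted p-values of the lists that changed follow, and the cause was not tested except where fewer arrays or genes entered. Under slide column and an estimated correlation, these lost the threshold: AhR targets 0.0603, CAR and PXR targets 0.0603, NRF2 and oxidative stress 0.356, cholesterol synthesis 0.703, lipogenesis 0.686, fatty acid oxidation and ketogenesis 0.356, glucose metabolism 0.631, growth hormone and IGF axis 0.375, thyroid hormone 0.375, cell cycle 0.631, acute phase and inflammation 0.495, interferon response 0.631, oxidative phosphorylation 0.631, ribosomal proteins 0.686, periportal hepatocyte 0.356, hepatocyte 0.356, Kupffer cell and macrophage 0.669 and neutrophil 0.631. Under slide column and an estimated correlation, these turned direction: retinoid metabolism 0.905. Under an estimated correlation, these lost the threshold: NRF2 and oxidative stress 0.108, cholesterol synthesis 0.468, lipogenesis 0.414, fatty acid oxidation and ketogenesis 0.187, glucose metabolism 0.290, growth hormone and IGF axis 0.155, thyroid hormone 0.118, cell cycle 0.285, acute phase and inflammation 0.263, interferon response 0.270, oxidative phosphorylation 0.155, ribosomal proteins 0.319, periportal hepatocyte 0.108, hepatocyte 0.145, Kupffer cell and macrophage 0.285 and neutrophil 0.270. Under column 1 alone, these turned direction: metallothioneins and zinc transport 0.696, bile acid synthesis and transport 0.696, sex-dependent liver genes 0.575, methylation and one-carbon metabolism 0.756, cell cycle 0.0552 and ER stress 0.696. Under column 1 alone, these lost the threshold: lipogenesis 0.220, glucose metabolism 0.220, growth hormone and IGF axis 0.288, thyroid hormone 0.0539, oxidative phosphorylation 0.674, ribosomal proteins 0.654, hepatocyte 0.220 and neutrophil 0.385. Under column 1 alone, these gained it: pericentral hepatocyte 0.0340, stellate and fibroblast 0.00497 and erythroid 3.13e-05. Under processed signals, these turned direction: bile acid synthesis and transport 0.822 and ribosomal proteins 0.991. Under processed signals, these lost the threshold: lipogenesis 0.0742, glucose metabolism 0.0511, growth hormone and IGF axis 0.0622, thyroid hormone 0.0724, oxidative phosphorylation 0.0724, Kupffer cell and macrophage 0.179 and neutrophil 0.269. Under the filter on all 8 arrays, these turned direction: bile acid synthesis and transport 0.984 and immediate early genes 0.984. Under the filter on all 8 arrays, these lost the threshold: glucose metabolism 0.0547. Under Cy5 alone, these lost the threshold: glucose metabolism 0.316, oxidative phosphorylation 0.269, ribosomal proteins 0.316 and hepatocyte 0.409. Under Cy5 alone, these gained it: sex-dependent liver genes 0.0196, pericentral hepatocyte 0.00732 and erythroid 0.00119. The pericentral list holds Cyp1a2, at 1.54 in Cy5 against a list median of 0.06. The sex-dependent list holds Cyp2c7, at 1.90 in Cy5 against a list median of -0.05. Under Cy5 alone, these turned direction: circadian clock 0.926. Under no filter, these lost the threshold: glucose metabolism 0.0734. Under no filter, these gained it: sex-dependent liver genes 0.0345. Under no filter, these turned direction: circadian clock 0.891 and retinoid metabolism 0.952. Under slide column as a covariate, these lost the threshold: glucose metabolism 0.112. Under slide column as a covariate, these turned direction: retinoid metabolism 0.816. Under column 2 alone, these lost the threshold: glucose metabolism 0.0731, interferon response 0.162 and Kupffer cell and macrophage 0.246. Under column 2 alone, these gained it: sex-dependent liver genes 0.000293 and fetal liver genes 0.0479. Under column 2 alone, these turned direction: circadian clock 0.689, retinoid metabolism 0.646, immediate early genes 0.492, pericentral hepatocyte 0.689, stellate and fibroblast 0.0345 and erythroid 0.0345. Under slide row as a block, these turned direction: circadian clock 0.953 and ER stress 0.961. Under slide row as a block, these gained it: fetal liver genes 0.00804. Under median centring, these lost the threshold: oxidative phosphorylation 0.246 and ribosomal proteins 0.463. Under median centring, these gained it: fetal liver genes 0.0356. Under deposited values, these lost the threshold: oxidative phosphorylation 0.111 and ribosomal proteins 0.591. Leaving out 1 array at a time, the adjusted p ranged as follows for lists that changed: metallothioneins and zinc transport 0.103 to 0.837, cholesterol synthesis 1.46e-11 to 0.0907, bile acid synthesis and transport 0.141 to 0.873, lipogenesis 1.84e-05 to 0.828, glucose metabolism 0.00299 to 0.281, sex-dependent liver genes 0.00548 to 0.894, thyroid hormone 0.00106 to 0.0595, cell cycle 2.28e-08 to 0.0905, acute phase and inflammation 4.95e-05 to 0.306, circadian clock 0.629 to 0.955, ER stress 0.405 to 0.994, retinoid metabolism 0.570 to 0.998. For the rest it ranged as follows: oxidative phosphorylation 0.00411 to 0.226, ribosomal proteins 7.81e-05 to 0.139, immediate early genes 0.395 to 0.954, fetal liver genes 0.00632 to 0.457, pericentral hepatocyte 0.0179 to 0.949, periportal hepatocyte 0.00119 to 0.0514, endothelial 0.141 to 0.994, stellate and fibroblast 0.340 to 0.715, Kupffer cell and macrophage 0.000145 to 0.213, lymphocyte 0.0367 to 0.500, neutrophil 1.62e-05 to 0.258 and erythroid 0.0188 to 0.821.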

Other observations

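With slide column fitted and Cy5 alone, a combination chosen after the data were examined, 14 genes passed the threshold in limma, all higher in the mixture group, 4 of them probes with no gene name here. Cyp1a1 and Cyp1a2 were among them, as were the CAR and PXR list members Cyp2b2, Cyp2c6v1, Akr7a3 and Ephx1. Cyp2c6v1, a constitutive hepatic P450, was 1.96-fold higher in Cy5 (log2 difference 0.97, SE 0.10, adjusted p = 0.00830), while its log2 ratio differed by 0.22. Gstm2 was 1.81-fold higher (adjusted p = 0.0450). Enpp2, which encodes the lysophospholipase autotaxin, was 1.37-fold higher (SE 0.06 on the log2 scale, adjusted p = 0.0313) and lies outside the rule for named genes. All of these Cy5 values lack the correction by the reference channel.

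Members of further lists passed over the list alone only with slide column fitted, and were chosen after their values were seen. Among clock genes, the output factor Dbp was higher by 0.76 (adjusted p = 0.00214 over the list alone). Of 18 NRF2 genes, 6 passed, all higher, among them the sulfiredoxin Srxn1 at 0.40 (adjusted p = 0.00450 over the list alone) and the glutathione peroxidase Gpx2 at 0.42 (adjusted p = 0.00330 over the list alone). Dbp, Srxn1 and Gpx2 passed over the list alone without each array. Me1 and Txn1, also among the 6 NRF2 genes, missed the threshold over the list alone without 4 and 5 of the single arrays. Of the sex-dependent liver genes 2 passed, both higher. Cyp2c11 differed by 0.57 (adjusted p = 0.0145 over the list alone, or 0.0600 without control replicate 5). Cyp2c7, at 1.63, passed over the list alone without each array. The clock genes Cry1 and Nfil3, at -0.33 and -0.26, and the acute phase genes Fgb, Saa4 and Lbp, at -0.28, -0.24 and -0.49, passed on all 8 arrays but missed the threshold over the list alone without 5 to 8 of the single arrays.

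Cpb1, a pancreatic carboxypeptidase, differed by 1.95, with an adjusted p = 0.0245 over a list of 2 measured genes alone when slide column was fitted but 0.0842 without slide column in the fit, and with 2.51 in column 1 and 1.39 in column 2. The mean of the 2 pancreatic genes, relative to the control mean, was 3.61 on mixture replicate 4 and 1.64 on mixture replicate 1, but 0.58 on mixture replicate 2 and 0.01 on mixture replicate 3, with control arrays between -0.51 and 0.60, so that single pools stood apart. With slide column fitted, the difference of Cpb1 was 1.2045 without mixture replicate 4, and its adjusted p over the list alone was 0.0775 without mixture replicate 1, 0.0577 without control replicate 5, 0.0796 without control replicate 7 and 0.0592 without control replicate 8.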
